A study of Mus musculus with 6 samples.

How the data were processed

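Nuclear RNA and open chromatin were measured together, with the 10x Genomics Multiome assay, in nuclei from E12.5 mouse cochlea (C57BL/6J, unsorted). The labels list 6 samples, which are 1 ATAC library and 2 sequencing runs of the RNA library for each of 2 replicates, and the 1 matrix of each replicate was taken to hold both runs, which the labels do not state. The deposited matrices hold raw UMI counts per gene and nucleus and raw ATAC counts per peak and nucleus, per the file headers. The authors made these counts with Cell Ranger ARC 2.0.0 and the mm10 genome, per the submitters' processing notes, and no normalization by the authors is recorded. The gene model, the read filters and the use of strand in counting are not stated. Peaks were called in each replicate separately, since the peak lists differ (235720 and 229967 peaks), and each matrix has 32285 genes. Of the ATAC values 83.0% and 82.8% are even, as counts of cut sites (a pair per fragment) would be, so they were used as deposited and, as an alternative, halved and rounded up.

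Nuclei were kept with at least 1000 UMIs, at least 1000 ATAC counts and at most 10% mitochondrial UMIs. In replicates 1 and 2 these limits removed 171 and 186 nuclei for UMIs, 733 and 593 for ATAC counts and 0 and 0 for mitochondrial UMIs, some of them for more than 1 reason, and left 13639 and 12024. Scrublet's method, as implemented in scanpy 1.11.5 with an expected rate of 10%, called 2938 (21.5%) and 2356 (19.6%) of them doublets, which were removed. That is more than the expected rate, and the called nuclei had medians of 13865 and 12784.5 UMIs against 5786 and 5561 in the others. The nuclei used were 10701 and 9668.

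Before the data were examined, genes were split by a seeded draw into a clustering part (16105 genes) and a held-out part (16180 genes). The cell type markers were forced into the first and the 12 gene lists into the second, so that the clustering did not use the genes tested. The doublet calls used all genes, held-out ones included, so the choice of nuclei was not independent of the genes tested. The design, the tests, the gene lists, the markers, the rule for named genes and the alternatives were also fixed then, except those given here as added. Counts of the clustering part were scaled per nucleus and log-transformed, and 2000 variable genes, 40 principal components, 20 neighbours and Leiden resolution 1.0 gave 28 clusters over both replicates. A cluster took the name of the set with the highest score among 13 marker sets. The score was the mean of log2(CPM + 5) of the set's markers, scaled over the clusters and weighted towards markers high in few clusters. The chondrogenic and mural sets could name a cluster only where the mesenchyme set led the remaining sets. The scoring and its thresholds were chosen after the data were seen. The score had to be at least 0.5, at least 3 markers had to be raised, and no other set could have more markers among the 10 leading genes. A cluster whose median UMIs were under 0.333 of its samples' median also stayed unnamed if none of its set's markers were among those genes. Otic epithelium-like nuclei come from 11 clusters, periotic mesenchyme-like from 4, sensory neuron-like from 3 and each other class from 1. Several epithelium-like clusters scored only slightly above the next set, in the closest case 0.544 against 0.532 for the chondrogenic set. These thresholds left 4 clusters unnamed, with 4.85% and 4.25% of nuclei in replicates 1 and 2. Cluster 13 (385 and 349 nuclei) was left out for its leading genes, cluster 22 (101 and 46) for its low UMIs, and clusters 26 (22 and 10) and 27 (11 and 6) for their scores. As a check of the grouping, ATAC counts were clustered without RNA (50000 peaks, latent semantic indexing with 40 components). The ATAC clusters were named from the RNA of their nuclei with the same markers, so the names were not checked apart from RNA. The ATAC epithelium-like class was larger, with 7149 and 6393 nuclei against 6169 and 5561 by RNA, so it took in nuclei that RNA clusters had not named so. The ATAC classes held 82.1% and 81.6% of neuron-like and 99.9% and 99.9% of epithelium-like nuclei, 48.2% and 40.1% of chondrogenic, 68.4% and 76.0% of mesenchyme-like, 84.9% and 88.7% of endothelium-like and 97.3% and 99.0% of erythroid-like nuclei, and no ATAC cluster was named glia-like (0 of 141 and 0 of 134 nuclei).

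Raw counts were summed per class and replicate for classes with at least 50 nuclei in each replicate, which gave 7 classes. Held-out genes were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr) in R 4.3.3, in 1 fit over all class sums, without a replicate block. Passing meant a Benjamini-Hochberg adjusted p under 0.05 and a log2 fold change of at least 1 in size. The contrasts were neuron-like against otic epithelium-like nuclei, and neuron-like against the mean of the other 6 classes on the log scale, where each class weighs equally. A further fit replaced the neuron-like class with the neuron-like clusters, and compared those with the highest (late) and lowest (early) mean log2 CPM of Gap43, Stmn2, Nefl, Nefm, Ina and Snap25. In the contrast against the mean of the other 6 classes, the log level of a class with 0 counts has no lower bound. A gene or region with 0 counts in 1 of these classes can hardly be called lower there. Its log2 fold change depends on the prior count, and the calls of lower genes and regions in that contrast are a lower limit. Standard errors are the log2 fold change divided by the square root of F, and none is given for F under 1e-04. CPM of classes, of the late and early clusters and of regions are TMM-scaled, while CPM in the closing part are per 1e6 UMIs of the cluster without that scaling. The class sums of a replicate come from the same libraries, so the replicate numbers pair them. The log ratios of replicate 1 over replicate 2 correlated between classes at −0.133 to 0.683 (median 0.357) over 21 pairs of classes for RNA and at 0.0132 to 0.190 (median 0.0524) for ATAC. Gene lists were tested with limma 3.58.1 (camera with a preset correlation of 0.01 and with an estimated one, and fry). Of 36 list tests 22 passed with the preset and 16 with an estimated correlation. The calls lost are named beside each list. The symbol Drgx of the other cranial ganglion list is not in the files, which carry this gene as Prrxl1.

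Peaks of both replicates that overlap by at least 1 bp were merged into 210438 shared regions (median width 893 bp), which hold 89.3% and 91.6% of the peaks and 97.8% and 98.3% of the ATAC counts. Their counts were summed and tested as the genes were. Start sites and gene overlaps come from the positions in the files and from RefSeq on GRCm38.p6, the assembly of mm10, and coordinates count from 1. Start sites of genes and more accessible regions within 1 kb of them were compared by a two-sided Fisher's exact test over the genes tested that have such a region. Co-detection was the number of nuclei with UMIs of both genes over that expected from both rates in 10 bins of total UMIs, on nuclei thinned to 2000 UMIs, with exact Poisson intervals. Shares have exact binomial (Clopper-Pearson) 95% intervals, and all intervals cover counting error only.

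The rule for named genes took, for each gene comparison, the 14 highest and 8 lowest log2 fold changes among genes past the adjusted p, with the same sign in both replicates and at least 50 CPM in both replicates on the higher side, without clone names. For values below 0 against the other classes, that side is the highest of these classes and not their mean. It also took up to 3 members of each list with the largest changes among those that passed, the 6 highest and 4 lowest regions with at least 50 CPM on the higher side by the same rule, up to 6 regions past the thresholds at each study gene, and Isl1 and Pou4f1. Some genes and regions that this rule took are not reported here. The regions at the start sites of Isl1 and Pou4f1, the clusters described in the closing part and list members named as falling or not passing outside this rule were named after their values were seen.

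The tests were tested on simulated counts drawn from the overall means, trended dispersions and library sizes of the real sums. There were 200 changed features, 50 each at log2 fold changes of 1.5 up, 1.5 down, 3 up and 3 down. Changed features had at least 10 expected counts at the median library size, and all other features had the same mean share in every class. The simulation thus holds no differences between the other classes. It says little about features with 0 counts in a whole class, such as 129996 of the real regions. For genes against epithelium-like nuclei edgeR recovered 50, 49, 50 and 50 of them, with 0 unchanged of 7114 genes called. Against the other classes it recovered 50, 44, 50 and 48, with 3 called. Between late and early clusters it recovered 50, 49, 50 and 50, with 0 of 7429 called. For regions against epithelium-like nuclei it recovered 50, 35, 50 and 50, and against the other classes 50, 25, 50 and 46, with 4 of 184043 called in each.

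The alternatives were DESeq2 1.42.0 in place of edgeR, a replicate block, glmTreat against a log2 fold change of 1, no filter on low counts, 1 pooled sum of all other nuclei as the reference, called doublets kept, at least 2000 UMIs and 2000 ATAC counts, Leiden resolutions 0.5 and 2.0, another gene split, ATAC classes, reciprocal overlap of at least 50% for shared regions, binary ATAC counts, thinning to 1000 UMIs or none, 5 and 20 depth bins, a 5 kb promoter window and leaving out each replicate. Leaving out the erythroid-like class, halving the ATAC counts, the region counts at both study genes under the other fits and the class shares without each replicate were added after the data were seen. The alternatives with called doublets kept, the stricter nucleus filter, other resolutions, another gene split and ATAC classes clustered and named the nuclei anew. Their classes thus share names with the main classes but not all nuclei. A motif test was fixed but not run, since it needs the genome sequence. Groups of 2 samples are too small for a count over other splits. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, statsmodels 0.14.6 and matplotlib 3.10.9.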

Results

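Nuclei from the cochlea of mouse embryos at E12.5 were profiled with the 10x Genomics Multiome assay, which reads nuclear RNA and open chromatin (ATAC) from the same nucleus. The mice were of the inbred C57BL/6J strain and the nuclei were not sorted. The labels describe 1 group of 2 replicates, with no treatment or mutant, so every comparison is between cell classes of the same libraries and n = 2 throughout. Isl1 encodes a LIM-homeodomain transcription factor and Pou4f1 a POU-homeodomain transcription factor, and the series concerns the part that both play in inner ear sensory neurons. Replicate 1 held 14536 nuclei with 123767337 unique molecular identifiers (UMIs) and 345854050 ATAC counts. Replicate 2 held 12772 nuclei with 101095218 UMIs and 320444657 ATAC counts. The median nucleus had 6333 UMIs and 19688 ATAC counts in replicate 1, and 6044 UMIs and 21461 ATAC counts in replicate 2. The labels do not say whether the replicates came from separate litters or pools, so the p-values measure the spread between these 2 replicates, which may be technical.

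The dissected tissue was mostly otic epithelium-like, the epithelium that forms the cochlear duct, with a smaller population of sensory neuron-like nuclei. Otic epithelium-like nuclei made up 57.6% of the 10701 nuclei used in replicate 1 (exact binomial 95% interval 56.7 to 58.6) and 57.5% of 9668 in replicate 2 (56.5 to 58.5). Sensory neuron-like nuclei made up 10.3% (9.76 to 10.9) and 10.9% (10.3 to 11.5), or 1106 and 1053 nuclei. Periotic mesenchyme-like nuclei, named for the connective tissue around the inner ear, made up 17.9% (17.2 to 18.7) and 18.1% (17.3 to 18.9). The shares of chondrogenic otic capsule-like nuclei were 4.46% (4.07 to 4.87) and 4.35% (3.96 to 4.78). This share depends on the settings. Its mean was 11.5% with called doublets kept, and it was 1.44% and 1.40% at Leiden resolution 2.0 and 2.39% and 1.89% with ATAC classes. No cluster was named so at resolution 0.5, with the stricter nucleus filter or with another gene split. Endothelium-like nuclei made up 1.86% (1.61 to 2.13) and 1.92% (1.66 to 2.22), and glia and Schwann cell precursor-like nuclei 1.32% (1.11 to 1.55) and 1.39% (1.16 to 1.64). Erythroid-like nuclei made up 1.03% (0.846 to 1.24) and 1.01% (0.824 to 1.23). Melanocyte-like nuclei (42 and 36) and macrophage and other immune-like nuclei (20 and 20) were too few to test. Another 4.85% (4.45 to 5.27) and 4.25% (3.86 to 4.67) of nuclei stayed unnamed. Shares of large and small groups moved with the settings, by more than the counting intervals. The epithelium-like share was 49.7% and 50.2% with called doublets kept, 52.4% and 51.4% with another gene split and 66.8% and 66.1% with ATAC classes. The mesenchyme-like share was 23.6% and 23.7% at resolution 0.5 and 15.3% and 16.9% with ATAC classes. With at least 2000 UMIs and 2000 ATAC counts the unnamed share was 11.5% and 11.4% and the erythroid-like share 0.269% and 0.530%. The unnamed share was 8.24% and 7.67% at resolution 2.0, 8.05% and 8.50% with another gene split and 2.28% and 2.22% with called doublets kept, where the endothelium-like share was 2.91% and 2.73%. The intervals cover counting error only. The neuron-like share was 13.1% with called doublets kept and 8.82% when nuclei were classed from ATAC clusters.

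Isl1 RNA was present in both neuron-like and epithelium-like nuclei, while Pou4f1 RNA was high in neuron-like nuclei and low in each of the 6 other classes tested. Isl1 (ENSMUSG00000042258) reached 1024 and 1048 CPM (counts per 1e6 counts of the class sum, after TMM scaling) in neuron-like nuclei of replicates 1 and 2 and 405 and 414 CPM in epithelium-like nuclei. Pou4f1 (ENSMUSG00000048349) reached 245 and 240 CPM in neuron-like nuclei and 3.17 and 2.46 CPM in epithelium-like nuclei. In mesenchyme-like nuclei Isl1 stood at 19.5 and 21.8 CPM and Pou4f1 at 2.35 and 1.76 CPM. The question was in which classes of the cochlea each gene is higher than in others. Against epithelium-like nuclei the log2 fold change was 1.34 (SE 0.09, adjusted p = 2.48e-16) for Isl1 and 6.41 (SE 0.11, adjusted p = 1.56e-35) for Pou4f1, by edgeR's quasi-likelihood test with adjustment over the 12 contrasts of both genes. Against mesenchyme-like nuclei the values were 5.65 (SE 0.12, adjusted p = 8.34e-33) for Isl1 and 6.86 (SE 0.15, adjusted p = 4.95e-33) for Pou4f1. The log2 fold changes against chondrogenic, glia-like and endothelium-like nuclei were 5.53, 5.57 and 4.20 for Isl1 and 6.80, 6.34 and 6.03 for Pou4f1. Against erythroid-like nuclei they were 3.45 (SE 0.25) for Isl1 and 3.93 (SE 0.45) for Pou4f1, with adjusted p = 7.93e-16 and 2.03e-10 in edgeR. These values rest on few counts, since Pou4f1 was detected in 2 of 110 and 2 of 98 erythroid-like nuclei and Isl1 in 5 and 11. As class averages, both genes were higher in neuron-like nuclei in 2 of 2 replicates against each of the 6 classes. Isl1 varied between the clusters of both the neuron-like and the epithelium-like class. Not every neuron-like cluster need therefore exceed every epithelium-like cluster. With called doublets kept, nuclei were clustered and named anew, so the classes are not the same sets of nuclei. The chondrogenic class, for example, then had 1631 and 1336 nuclei in place of 477 and 421. The Isl1 difference was then 0.80 against epithelium-like nuclei, which is below the fold threshold of 1 (adjusted p = 5.42e-07 in edgeR). It was then 1.82 against chondrogenic, 2.25 against endothelium-like, 3.09 against glia-like and 1.28 against erythroid-like nuclei. The Pou4f1 difference against endothelium-like nuclei was then 3.74.

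**Figure D1:**
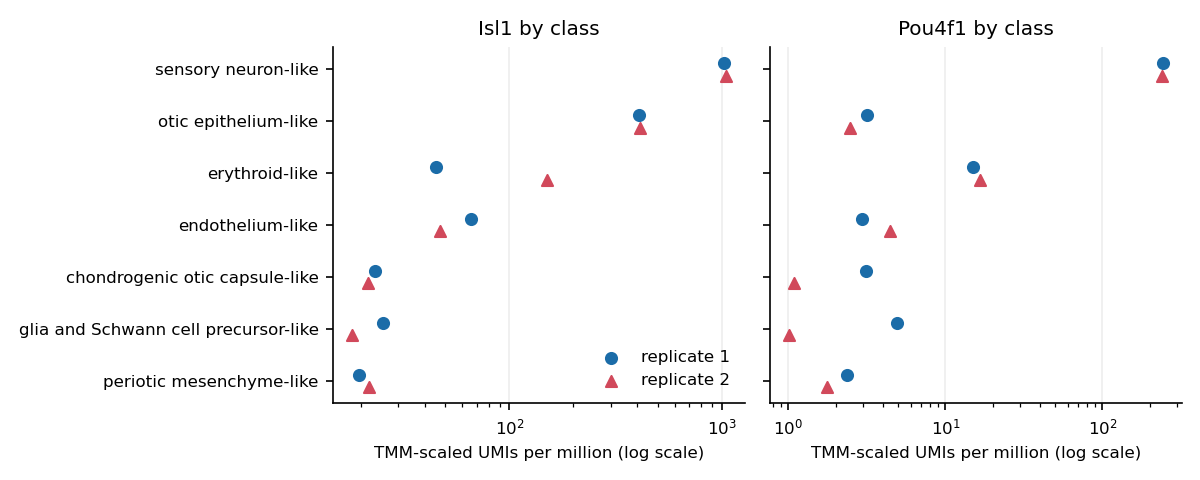
CPM of Isl1 and Pou4f1 (log axis) in 7 cell classes, with a circle for replicate 1 and a triangle for replicate 2. Isl1 stands at 1024 and 1048 CPM in neuron-like and at 405 and 414 CPM in otic epithelium-like nuclei, while Pou4f1 stands at 245 and 240 CPM in neuron-like nuclei and below 17 CPM in each other class.

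At the level of single nuclei, most Pou4f1-positive neuron-like nuclei also held Isl1 RNA, and the overlap was about what the separate rates give. Detection was compared after thinning each nucleus to 2000 UMIs, which left out 13 and 14 neuron-like nuclei and kept 1093 and 1039. Isl1 was detected in 75.6% of them (72.9 to 78.1) in replicate 1 and 79.0% (76.4 to 81.5) in replicate 2. Pou4f1 was detected in 32.0% (29.3 to 34.9) and 33.8% (30.9 to 36.7). Both genes were detected in 25.9% and 28.3% of neuron-like nuclei, and 80.9% and 83.8% of Pou4f1-positive nuclei held Isl1. The number with both was 1.04 times (0.927 to 1.17) and 1.04 times (0.927 to 1.17) that expected from independent genes within 10 depth bins. These Poisson intervals let the number with both vary freely although both rates were fixed, so they are too wide to exclude a small excess. Within the larger neuron-like clusters the ratio was 0.990 and 1.02 (cluster 8) and 1.01 and 0.978 (cluster 9). Isl1 was detected in 89.0% and 89.8% of nuclei in cluster 8 and in 63.1% and 63.6% in cluster 9. Without thinning, Isl1 was detected in 97.1% and 98.0%, Pou4f1 in 71.8% and 71.1%, and the ratio was 1.00 in each replicate. With Isl1 in nearly all nuclei that ratio could hardly leave 1, so it cannot show whether there is an excess. For comparison, mesenchyme-like nuclei had Isl1 in 3.44% and 3.79% and Pou4f1 in 0.591% and 0.467%, whether from free RNA in droplets or their own. In epithelium-like nuclei Isl1 was detected in 48.2% (46.9 to 49.4) and 48.4% (47.1 to 49.7), above those shares. Pou4f1 was detected there in 0.690% (0.498 to 0.932) and 0.562% (0.382 to 0.797), shares close to those of mesenchyme-like nuclei. Median depths before thinning were 8111 and 7654 UMIs in neuron-like, 5837 and 5549 in epithelium-like and 5327 and 5127.5 in mesenchyme-like nuclei.

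Inner ear neurons arise from the otic epithelium, and the next comparison asked which genes separate the neuron-like from the otic epithelium-like nuclei. On the neuron-like side, Alcam (ENSMUSG00000022636), a cell adhesion gene of growing axons, was higher by 8.97 on the log2 scale (SE 0.17), with 12472 and 11658 CPM against 25.7 and 22.4. Grin2a (ENSMUSG00000059003), an NMDA receptor subunit gene, was higher by 9.23 (SE 0.15), and Scn3a (ENSMUSG00000057182), a sodium channel gene, by 8.43 (SE 0.14). On the epithelium-like side stood Lmx1a (ENSMUSG00000026686), a LIM-homeodomain gene of non-sensory otic epithelium, and Pax2 (ENSMUSG00000004231), an early otic transcription factor gene. Their log2 fold changes were −5.35 (SE 0.14, adjusted p = 4.88e-29) and −5.11 (SE 0.14, adjusted p = 2.87e-28) in edgeR, with Lmx1a at 8.54 and 11.6 CPM against 423 and 396. Otogl (ENSMUSG00000091455), which encodes a protein of the acellular membranes of the inner ear, was lower by a log2 fold change of −5.16 (SE 0.17), and the thyroid hormone receptor gene Thrb (ENSMUSG00000021779) by −5.15 (SE 0.17). Further large increases were in Pcsk2, a prohormone convertase gene, and in Clvs1, Srrm3, Fam155a, Ano4, Dscaml1, Prmt8 and Ptpro, with log2 fold changes of 8.29 to 8.81. Further large decreases were in Adamts19, Acss3, Sntb1 and Cadps2, with values of −5.25 to −5.08. The antisense gene Nrg3os (9.37) and the microRNA host gene Mir124a-1hg (8.62) are uncertain, since whether the counting used strand is not stated. Of 7636 genes held out of the clustering, 2440 passed an adjusted p of 0.05 and a log2 fold change of 1 in size, 1212 higher and 1228 lower. The split was 1142 higher (62.9%) and 674 lower with called doublets kept, and 1248 higher and 1187 lower with DESeq2. All of these named genes had the same sign in 2 of 2 replicates, as the rule that named them required.

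In the neuron-like against epithelium-like comparison, the fixed gene lists split into neuronal groups that rose and proliferation and cochlear patterning groups that fell. The classes were named from other neuronal and epithelial genes. The direction of the neuronal and cochlear patterning lists is thus mainly a check of those names. Of 19 cytoskeleton and axonal transport genes 19 rose (camera adjusted p = 4.83e-16), among them Dnm3 (6.41), Prph (5.85) and Crmp1 (5.83). Of 27 voltage-gated and pacemaker channel genes 23 rose, 2 fell and 2 did not pass (camera adjusted p = 5.06e-13). Scn3a and the calcium channel gene Cacna1e (7.64) rose, while Kcnq3 was among those that fell. Of 22 synaptic transmission genes 19 rose, 1 fell (Gria3) and 2 did not pass (camera adjusted p = 2.18e-13). They include Gria2 (8.03), an AMPA receptor subunit gene, and Slc17a6 (7.67), a vesicular glutamate transporter gene. Of 20 neurogenic and sensory neuron transcription factor genes 14 rose and 6 did not pass (camera adjusted p = 1.58e-08), with Onecut1 (6.60), Shox2 (6.47) and Pou4f2 (6.35) highest. Most Onecut1 UMIs lay in neuron-like cluster 24 (39 and 24 nuclei), with 99 and 43 UMIs there, 8 and 4 in cluster 8 and 39 and 24 in cluster 9. Among those that did not pass were Eya1, Gata3 and Bcl11a. Of 38 axon guidance and adhesion genes 22 rose, 4 fell and 12 did not pass (camera adjusted p = 1.24e-07), with Epha5 (7.11), Sema3e (6.58) and Cntn2 (6.50) highest. Of 17 neurotrophin and trophic genes 8 rose, 7 fell and 2 did not pass (camera adjusted p = 0.491). The neurotrophin receptor genes Ntrk2 (7.74) and Ntrk3 (6.57) rose. Of 16 Notch pathway genes 7 rose, 5 fell and 4 did not pass (camera adjusted p = 0.853), with the ligand genes Dll1 (4.90) and Dll3 (4.51) and the glycosyltransferase gene Mfng (4.68) highest. Of 15 apoptosis and survival genes 2 rose, 2 fell and 11 did not pass (camera adjusted p = 0.511). The survival gene Bcl2 (−3.08) and the pro-apoptotic gene Bcl2l11 (−2.32) fell.

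On the epithelium-like side of the same comparison, 15 of 17 prosensory and cochlear duct patterning genes fell and 2 (Sall4 and Cdkn1b) did not pass (camera adjusted p = 1.02e-11). Msx1 (−4.23) fell with Lmx1a and Pax2. Of 26 proliferation genes 25 fell and Ccnb2 did not pass (camera adjusted p = 5.06e-13), with the mitotic genes Kif15 (−3.09), Bub1 (−3.06) and Kif11 (−2.95) lowest. Of 3 genes that mark other cranial ganglia 2 rose, among them the growth factor receptor gene Ret (5.75). Hmx1 of this list was not tested, and it had 31 and 19 UMIs (60.6 and 59.6 CPM, unscaled) in neuron-like cluster 24. The camera adjusted p for this list was 0.0423, with adjusted p = 0.132 with an estimated correlation and adjusted p = 0.0822 with the replicate block. Isl1 and Pou4f1 both rose. In each of the 12 lists the counts adjusted over the list alone were those over all genes tested. Epithelium-like nuclei pool 11 clusters, so the values are averages over unlike regions of the epithelium.

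The same neuron-like nuclei were then set against the mean of the 6 other classes, to ask which genes mark them in the whole tissue. Mapk10 (ENSMUSG00000046709), a neuron-enriched stress-activated kinase gene, was higher by a log2 fold change of 9.18 (SE 0.11) and reached 558 and 534 CPM. Csmd1 (ENSMUSG00000060924), which encodes a complement control protein, was higher by 8.46 (SE 0.10) and reached 3737 and 3340 CPM. Grxcr1 (ENSMUSG00000068082), known for its part in hair cell stereocilia, was higher by 9.36 (SE 0.23, adjusted p = 1.77e-28 in edgeR), with 91.8 and 88.2 CPM against 0.434 and 0.128. Further large increases, with log2 fold changes of 8.35 to 9.35, were in Prmt8, Nyap2, Shisal1, Cntn2, Pcsk2, Grin2a, Fam155a, Clvs1 and Gdap1, and in the uncertain antisense gene Nrg3os. Tcf7l2 (ENSMUSG00000024985), a Wnt pathway transcription factor gene, had a log2 fold change of −4.70 (SE 0.12, adjusted p = 9.24e-30 in edgeR). Lama4, a laminin gene of vessel walls, had −4.55 (SE 0.46), and the values of Sgk3, Gulp1, Depdc1b and Slc43a3 lay between −5.12 and −4.42. Bcl6b had 1 UMI in neuron-like nuclei, and its rate in the other classes was 64.6 times as high (11.5 to 2559). Of 7636 genes 2305 passed, 1521 higher (66.0%) and 784 lower. None of the 1729 genes with 0 counts in at least 1 of the 6 classes could be called lower by this contrast (703 higher, 0 lower), so the split is biased towards higher genes. Of the 5907 other genes 818 were higher and 784 lower. The 6 classes weigh equally in this mean. The split moved with this weighting and also with the classes, the genes, the scaling and the test used. The share of higher genes was 44.3% (1515 of 3423) against 1 pooled sum of all other nuclei, 54.0% without the erythroid-like class, 54.7% with DESeq2, 54.8% with another gene split and 55.2% with ATAC classes. The share rose to 73.4% (978 of 1333) with called doublets kept and to 68.0% at resolution 0.5 and without the low-count filter.

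Against the mean of the other classes, neuronal groups again stood high, which is likewise mainly a check of the class name. Of 20 neurogenic and sensory neuron transcription factor genes 18 rose and 2 did not pass (camera adjusted p = 1.10e-14), with Onecut1 (9.09, mostly from cluster 24), Shox2 (6.61) and Pou4f2 (6.42) highest. All 19 cytoskeleton and axonal transport genes rose (camera adjusted p = 3.11e-19), with Stmn4 (6.73), Prph (6.31) and Kif5a (6.08) highest. Of 27 channel genes 25 rose and 2 did not pass (camera adjusted p = 2.30e-17), with Kcnc1 (8.66) and Cacna1b (8.19) among the highest. Of 22 synaptic transmission genes 18 rose and 4 did not pass (camera adjusted p = 1.13e-16), with Cplx1 (8.54) and Slc17a7 (8.26) highest. Of 38 axon guidance genes 28 rose, Slit3 fell and 9 did not pass (camera adjusted p = 4.21e-18), with Cntn2 (8.62), Sema3e (6.96) and Epha5 (6.89) highest. Of 17 trophic genes 8 rose, 3 fell (Met, Ntf3 and Erbb2) and 6 did not pass (camera adjusted p = 0.00696), with adjusted p = 0.141 with an estimated correlation. Ntrk3 (7.68), Ntrk2 (6.65) and the neuregulin gene Nrg1 (5.74) were highest. All 26 proliferation genes fell (camera adjusted p = 8.77e-14), with Kif15 (−3.43), Kif11 (−3.37) and Bub1 (−3.27) lowest. Of 17 prosensory and cochlear duct genes 2 rose, 10 fell and 5 did not pass (camera adjusted p = 0.00120), with adjusted p = 0.0564 with an estimated correlation. Sall4 (2.87) rose and the signalling gene Bmp4 (−1.99) fell. Lfng (−1.95) also fell, but its value was −0.56 without replicate 1. Of 16 Notch genes 7 rose, 4 fell (Notch1, Notch2, Hey1 and Hes1) and 5 did not pass (camera adjusted p = 0.482), with Dll1 (6.21), Dll3 (4.23) and Jag2 (3.79) highest, and Dll3 at 6.36 without replicate 1. Of 15 apoptosis genes 4 rose, 2 fell and 9 did not pass (camera adjusted p = 0.255), with Bcl2l2 (2.02) and Bcl2 (−2.14) among those that passed. The median of that list was −0.02, its mean 0.12, camera's direction down and fry's direction up. Of 3 other cranial ganglion genes 2 rose, among them Ret (6.94), and 1 did not pass (camera adjusted p = 0.0520). Isl1 (4.29, SE 0.08) and Pou4f1 (6.06, SE 0.10) both rose. Counts adjusted over the list alone were those over all genes tested.

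Within the neuron-like class, the 2 clusters with enough nuclei were compared, to ask which genes differ between them. They were called late (528 and 466 nuclei) and early (539 and 563 nuclei) after a score of 6 neuronal maturation genes, which differed only from 8.88 to 8.50 mean log2 CPM, so the names rest on a small difference. Both clusters come from a single age, so stages and types of neuron cannot be told apart here. Cdh18 (ENSMUSG00000040420), a cadherin gene, was higher in the late cluster by a log2 fold change of 8.20 (SE 0.18, adjusted p = 2.97e-35 in edgeR), with 1239 and 1175 CPM against 4.79 and 3.39. The potassium channel gene Kcnc2 (5.45, SE 0.13), the mu-opioid receptor gene Oprm1 (5.17, SE 0.18), the semaphorin receptor genes Plxna4 (4.54, SE 0.15) and Nrp1 (3.94, SE 0.18) and the adhesion gene Chl1 (4.45, SE 0.13) were also higher there. Nrp2 (ENSMUSG00000025969), the other neuropilin gene, was lower in the late cluster by a log2 fold change of −4.07 (SE 0.13, adjusted p = 2.21e-29 in edgeR), with 25.8 and 21.0 CPM against 408 and 380. Robo2, a Slit receptor gene, had −3.20 (SE 0.12), and the protocadherin gene Pcdh17 had −2.84 (SE 0.11). Zfp804b (5.92), Sgk1 (4.84), Lrrtm3 (4.70), Dok6 (4.26), Pcdh15 (3.53), Ano3 (3.34) and Bmper (3.29) were higher, and Cdhr1 (−3.79), Mfap4 (−3.56), Lingo2 (−2.96), Inka2 (−2.72) and Rnf152 (−2.70) lower. The uncertain antisense gene Nrg3os had 2 UMIs in the early cluster, and its rate in the late cluster was 304 times as high (83.8 to 2515). Isl1 stood at 1464 and 1462 CPM in the early and 688 and 660 CPM in the late cluster, a log2 fold change of −1.12 (SE 0.10, adjusted p = 3.92e-13 in edgeR). Pou4f1 stood at 313 and 287 CPM in the early and 187 and 192 CPM in the late cluster, a log2 fold change of −0.66 (SE 0.09, adjusted p = 4.86e-08 in edgeR) that is below the fold threshold. Of 7920 genes 588 passed, 366 higher and 222 lower in the late cluster. With called doublets kept, a new clustering gave neuron-like clusters numbered 8, 9 and 13, and the late and early clusters were picked anew among them. Between that other pair 1875 genes passed, 725 higher and 1150 lower, so these counts are not of the same comparison. With a test against the fold threshold itself (glmTreat) 271 passed, 169 higher and 102 lower.

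**Figure D2:**
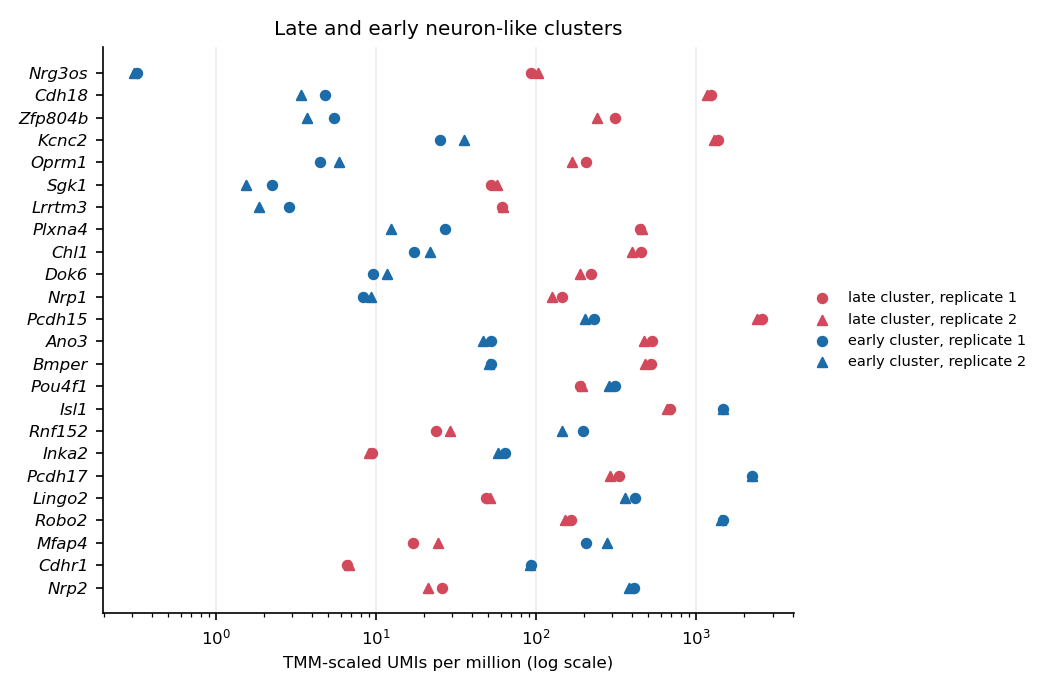
CPM (log axis) of the 22 genes with the largest changes and of Isl1 and Pou4f1 in the late and the early neuron-like cluster, with a marker per replicate. Cdh18 lies at 1239 and 1175 CPM in the late and 4.79 and 3.39 CPM in the early cluster, and Nrp2 at 25.8 and 21.0 against 408 and 380 CPM.

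Between the late and early clusters, 5 of the 12 fixed lists had members past the thresholds in both directions. Genes said to rise were higher in the late cluster and those said to fall were lower there, with no time course implied. Of 38 axon guidance genes 10 rose, 4 fell and 24 did not pass, with 11 rising and 4 falling when adjusted over the list alone (camera adjusted p = 0.00653; adjusted p = 0.227 with an estimated correlation). Of 27 channel genes 9 rose, 4 fell and 14 did not pass, with 10 rising and 4 falling when adjusted over the list alone (camera adjusted p = 0.0103; adjusted p = 0.0757 with an estimated correlation). Kcna1 (3.13), Kcnq3 (3.06) and Cacna1c (2.52) rose most. Of 19 cytoskeleton genes Prph (3.11) and Kif21b (3.05) rose and 17 did not pass (camera adjusted p = 0.00653; adjusted p = 0.136 with an estimated correlation). Of 20 transcription factor genes 5 rose, 4 fell and 11 did not pass (camera adjusted p = 0.0576, and 0.0251 with the replicate block, where an estimated correlation gave 0.0952). Runx1 (3.16), Pou4f2 (3.13) and Onecut1 (2.15) rose, while Neurod1, Insm1, Eya2 and Prox1 fell. The median of that list was −0.38, its mean 0.12 and camera's direction down. Of 23 synaptic genes 5 rose, 3 fell and 15 did not pass (camera adjusted p = 0.851), with the calcium-binding protein gene Calb1 (2.89) and Gria3 (2.19) rising and the vesicular glutamate transporter gene Slc17a7 (−2.35) falling. Of 16 Notch genes Dll1 (1.69) rose, 4 fell, among them Mfng (−2.55) and Dll3 (−1.97), and 11 did not pass (camera adjusted p = 0.0686). Of 17 trophic genes Fgfr1 (1.59) rose and 16 did not pass, with 2 rising when adjusted over the list alone (camera adjusted p = 0.883; median −0.03, mean 0.33, camera and fry directions down). Of 3 other cranial ganglion genes 1 fell and 2 did not pass (camera adjusted p = 0.213). None of the 15 apoptosis (camera adjusted p = 0.851), 17 prosensory (0.883) and 26 proliferation genes (0.883) passed in edgeR, where 5, 5 and 4 of them had an unadjusted p under the threshold, and 0 of each passed in DESeq2. Of the study genes Isl1 fell and Pou4f1 did not pass the fold threshold (camera adjusted p = 0.000169). In the other lists the counts adjusted over the list alone were those over all genes tested.

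**Figure D3:**
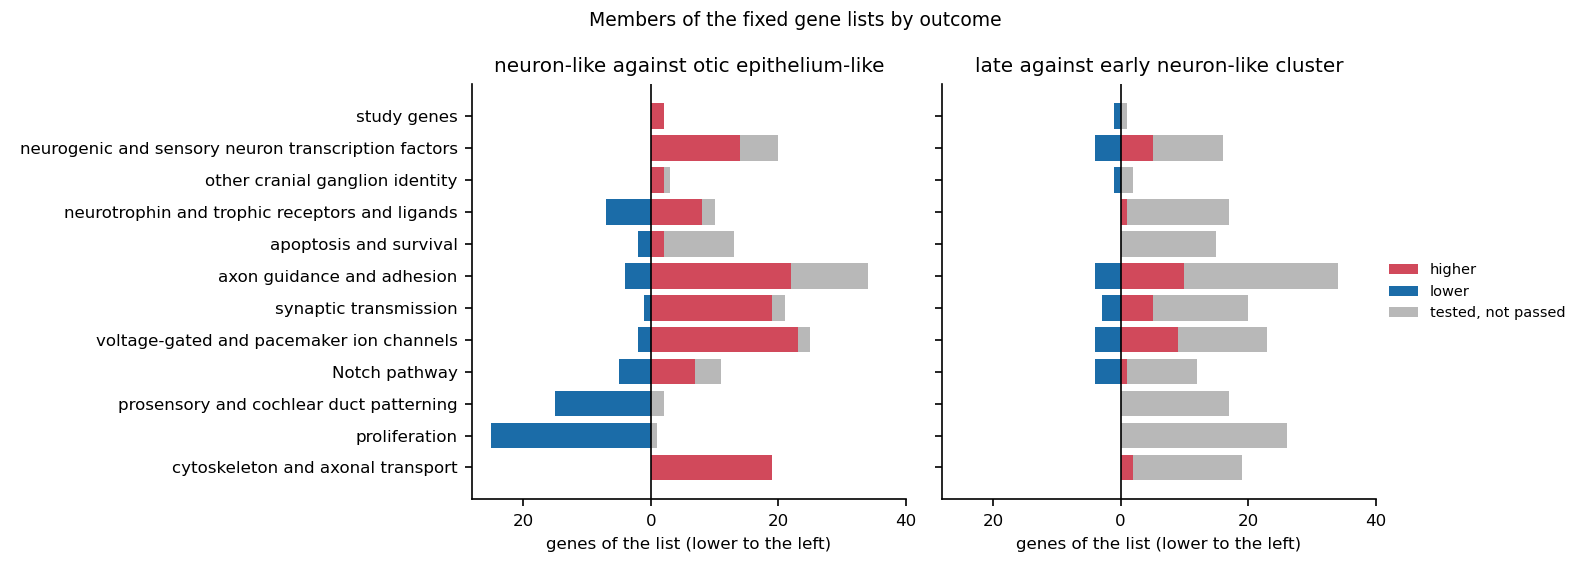
Number of members of each fixed gene list (x axis, genes) that were higher, lower or not past the thresholds, for neuron-like against otic epithelium-like nuclei and for the late against the early neuron-like cluster. In the first panel 19 of 19 cytoskeleton genes are higher and 25 of 26 proliferation genes lower, and in the second 0 of 26 proliferation genes pass.

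Open chromatin also separated the neuron-like nuclei, both at gene starts and far from them. A region at the start of Tmem178b, which encodes a membrane protein (chromosome 6, 40019118 to 40020015, mm10), had 63.0 and 60.1 CPM in neuron-like and 0.213 and 0.219 CPM in epithelium-like nuclei, a log2 fold change of 8.12 (SE 0.20). A region at a start site of Sox2ot, a long noncoding RNA gene that overlaps Sox2 (chromosome 3, 34322438 to 34323277), was more accessible by 7.32 (SE 0.18). A region within the kinase gene Nek11 (chromosome 9, 105379487 to 105380398) was more accessible by 7.79 (SE 0.19). A region on chromosome 5 (28838026 to 28838914) that lies 357 kb from the nearest start site, that of Rnf32, was more accessible by 8.15 (SE 0.21). Less accessible were a region within Cryl1 (chromosome 14, 57315399 to 57316323; log2 fold change −4.25, SE 0.16, adjusted p = 2.77e-149 in edgeR) and a region at a start site of BC006965 (chromosome 11, 112711320 to 112712262; −4.12, SE 0.15, adjusted p = 7.25e-175). Exon and intron positions were not used here. Of 200324 regions 94667 passed against epithelium-like nuclei, 40908 more accessible (43.2%) and 53759 less. Keeping called doublets turned the split, to 41858 more accessible (56.7%) and 31930 less. Of the more accessible regions 15.3%, of the less accessible 14.7% and of all tested regions 20.5% lay within 1 kb of a start site.

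Against the mean of the other classes, the same regions of Tmem178b (11.67, SE 0.26), Nek11 (9.43, SE 0.22) and chromosome 5 (9.81, SE 0.23) were among the 6 with the largest log2 fold changes among regions of at least 50 CPM. Regions within Thsd7b (chromosome 1, 129473238 to 129474142; 8.38, SE 0.21) and Cerkl (chromosome 2, 79414146 to 79415068; 8.25, SE 0.22) followed. In replicates 1 and 2 alone the values were 10.85 and 7.89 for Thsd7b, 9.45 and 7.93 for Cerkl and 9.48 and 11.79 for chromosome 5. They lay closer for Tmem178b (11.61 and 11.78) and Nek11 (9.32 and 9.56). For Thsd7b, Cerkl and chromosome 5 the SE is thus smaller than the spread between replicates. Where a class has 0 counts, the size of such values depends on the prior count. Among the less accessible regions, the start site of Zfp36l1, an RNA-binding protein gene, had a log2 fold change of −3.25 (SE 0.12; chromosome 12, 80112770 to 80113682). Of 200324 regions 69622 passed, 62549 more accessible (89.8%) and 7073 less. Of them 129996 had 0 counts in at least 1 of the 6 classes, and these gave 49712 more and 0 less accessible regions, against 12837 and 7073 among the other 70328. The median of all regions was 0.92 and not 0, and the split also moved with the classes, their weighting, the nuclei, the scaling and the test used. The stricter nucleus filter left no erythroid-like or chondrogenic class to test. The split was 62.7% more accessible (47736 of 76162; median 0.16) without the erythroid-like class, 75.3% (59358 of 78823; median 0.33) with DESeq2, 62.1% with the stricter nucleus filter and 41.3% (40344 of 97726; median −0.09) against 1 pooled sum. When called doublets were kept 37686 regions passed, and 43318 passed the test against the fold threshold itself.

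Regions around the study genes showed a dense set of neuron-accessible regions at Pou4f1 and a mixed set at Isl1. Within 100 kb of the Pou4f1 start site (chromosome 14, 104467999) 25 regions were tested against epithelium-like nuclei, of which 17 were more accessible in neuron-like nuclei, 2 less and 6 did not pass. The region 1.44 kb from the start (104469440 to 104470388) had 54.3 and 49.9 CPM against 1.57 and 1.90, a log2 fold change of 4.90 (SE 0.15, adjusted p = 8.50e-221 in edgeR). The region 77.8 kb away (104389287 to 104390167) was more accessible by 7.33 (SE 0.42, adjusted p = 9.64e-66), and the region 28.1 kb away (104439521 to 104439921) by 5.69 (SE 0.53, adjusted p = 1.17e-25). Both lie nearer to D130079A08Rik, whose start site is 69.1 and 19.4 kb away. Regions were counted by distance alone and not assigned to a gene. The start site itself (104467594 to 104468462) had a log2 fold change of 0.68, below the fold threshold, with 48.6 and 50.5 CPM against 31.4 and 30.6. Within 100 kb of the Isl1 start sites (chromosome 13, 116309422 to 116309689) 17 regions were tested, of which 3 were more accessible in neuron-like nuclei, 5 less and 9 did not pass. The region 23.8 kb away (116284725 to 116285651) was less accessible, at 0.657 and 1.05 CPM against 7.67 and 6.77 (log2 fold change −3.06, SE 0.34, adjusted p = 6.44e-19 in edgeR), as was the region 52.8 kb away (116255745 to 116256666; −2.58, SE 0.41, adjusted p = 9.17e-10). The region 92.7 kb away (116215995 to 116216710) was more accessible by 1.96 (SE 0.48, adjusted p = 1.23e-04). The Isl1 start (116309347 to 116310252) had 0.37, below the fold threshold. Among all tested regions 20.4% were more and 26.8% less accessible.

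Against the mean of the other classes, 18 of 25 regions at Pou4f1 and 12 of 17 at Isl1 were more accessible and 0 less, where 31.2% of all tested regions were more and 3.53% less accessible. The region 3.65 kb from the Isl1 start (116313338 to 116314235) had a log2 fold change of 3.87 (SE 0.29, adjusted p = 8.26e-40 in edgeR), and the region 10.4 kb from the Pou4f1 start (104456709 to 104457555) had 5.47 (SE 0.25, adjusted p = 4.99e-105). That Pou4f1 region lies 1.76 kb from the start site of D130079A08Rik. The Isl1 region 23.8 kb away shows the effect of averaging on the log scale over classes with few or 0 counts, since its log2 fold change was 3.77 although its 0.657 and 1.05 CPM lay below the mean of the other classes, 1.33 and 1.25 CPM. The same holds for the Pou4f1 region 94.1 kb away (104562106 to 104563004), with a log2 fold change of 3.90 at 1.12 and 1.80 CPM against 2.10 and 2.00. With called doublets kept, 14 regions at Pou4f1 and 4 at Isl1 passed.

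**Figure D4:**
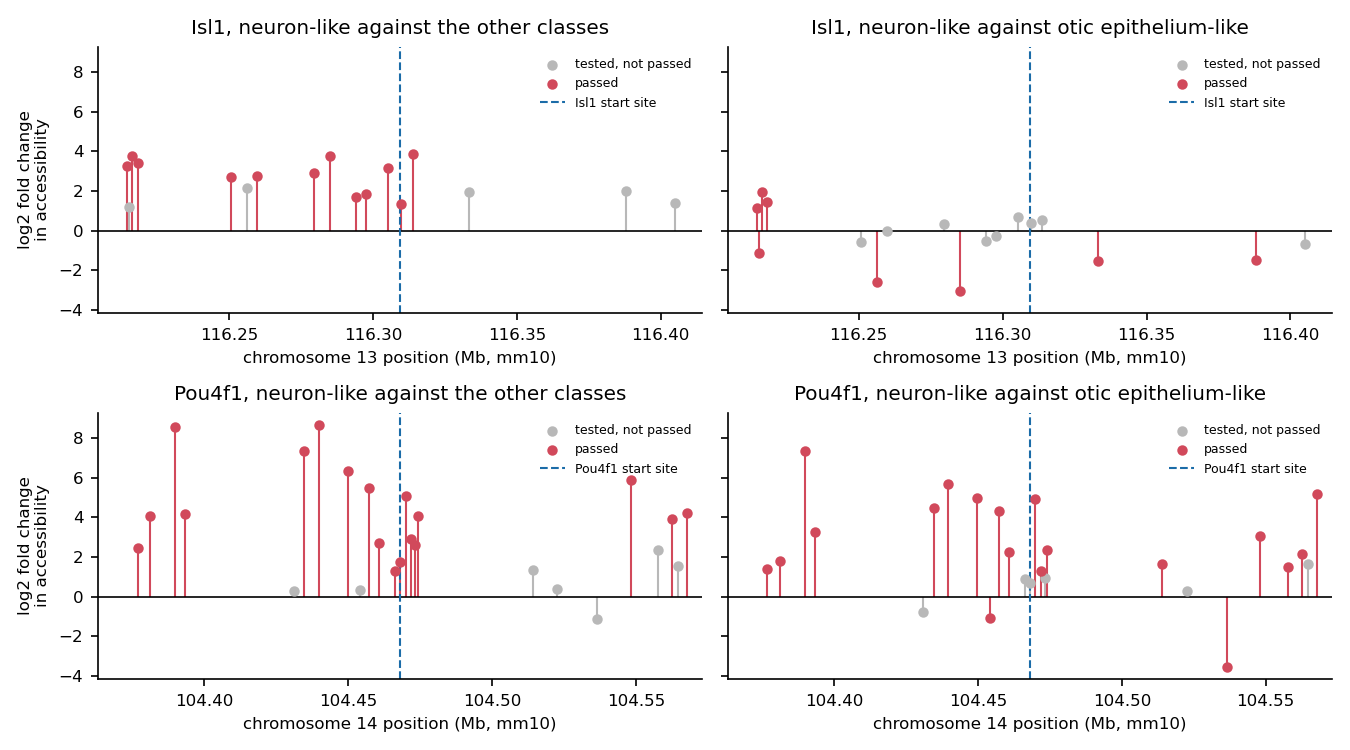
Log2 fold change of accessibility (y axis) of each tested region within 100 kb of the Isl1 and Pou4f1 start sites (x axis, mm10 position), against the other classes and against otic epithelium-like nuclei, with regions past both thresholds in red and the others in grey. Against epithelium-like nuclei 17 of 25 regions at Pou4f1 lie past the thresholds above 0, and 3 of 17 at Isl1.

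RNA and chromatin at gene starts were compared next, as separate readouts of the same nuclei. Of 1103 genes with higher RNA in neuron-like than in epithelium-like nuclei, 406 (36.8%) had a more accessible region within 1 kb of a start site, against 5.92% of the other genes (odds ratio 9.27, two-sided Fisher's exact test, adjusted p = 3.24e-152). Of 1184 genes with lower RNA, 441 (37.2%) had a less accessible region, against 10.2% (odds ratio 5.22, adjusted p = 3.81e-104 by the same exact test). Against the mean of the other classes, 771 of 1387 genes with higher RNA (55.6%) had a more accessible region, against 11.4% (odds ratio 9.75, adjusted p = 1.69e-253). Of 759 genes with lower RNA 132 (17.4%) had a less accessible region, against 3.91% (odds ratio 5.18, adjusted p = 8.46e-39). The p-values treat genes as independent, which they are not. Against the other classes both sets of calls also share a bias. Features with 0 counts in a class made up 703 of the 1521 higher genes and 49712 of the 62549 more accessible regions, and 0 were called lower. The odds ratio of 9.75 may rest partly on such features, which was not tested. The comparison with epithelium-like nuclei does not average over classes.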

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

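Apart from the test of regions with the highest mean, the tests in this part were chosen after the results were seen, as were the clusters and genes named in it.

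UMIs of both study genes were found in unnamed clusters, whose nuclei belong to no class of the main comparisons. Unnamed cluster 26 (22 and 10 nuclei) held 132 UMIs of Isl1 and 8 UMIs of Pou4f1 over both replicates, and unnamed cluster 27 (11 and 6 nuclei), led by the platelet genes Pf4, Ppbp and Itga2b, held 60 UMIs of Isl1. Unnamed cluster 22 (101 and 46 nuclei) held 104 and 43 UMIs of Isl1 (641 and 552 CPM) in replicates 1 and 2. Unnamed cluster 13 (385 and 349 nuclei) held 57 and 27 UMIs of Isl1 (28.4 and 14.8 CPM) and 6 and 4 UMIs of Pou4f1. These counts were not tested against free RNA.

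Cluster 26 was led by the neurogenic gene Neurod1 (816 and 722 CPM) and Prdm12. It had Isl1 at 664 and 756 CPM, Eya2 at 1297 and 1696 CPM and the proliferation gene Mki67 at 458 and 655 CPM, with Neurog1 at 2 and 1 UMIs. Doublets of neuron-like and epithelium-like nuclei are argued against as its whole source, since a mixture cannot exceed both of its sources. Of 545 genes with at least 20 UMIs in each replicate, 24 had over 2 times the CPM of every neuron-like and epithelium-like cluster in both replicates. Eya2, for example, reached at most 203 and 179 CPM in those clusters. The summed CPM of the 8 genes lowest in neuron-like against epithelium-like nuclei reached 17.2% of the epithelial level in the higher replicate (2.33% in neuron-like nuclei), so some doublets are not excluded. Nuclei of another cranial ganglion are a candidate explanation, and of 9 genes that mark such ganglia only 1, Prdm12, had more CPM than in neuron-like nuclei in both replicates. That value lay between its bounds, so this stays open, and no other biological explanation was tested, since the labels give a single group.

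Against the mean of the other classes, 89.8% of the regions that passed were more accessible in neuron-like nuclei. Low counts in small classes are left open by the test set for them, in which 84.8% of the 17209 calls were more accessible among the 25% of regions with the highest mean (50081 regions). That test is void, since 15538 of these regions still have 0 counts in a whole class. Counts of 0 in a whole class may account for much of the excess, since at such regions the contrast called none less accessible, while 1 pooled sum of the other nuclei gave 71657 calls there, 42.7% of them more accessible. The erythroid-like class, which has the fewest ATAC counts, may account for part of the excess, since the share was 62.7% without it. The pooled sum also weighs the classes by size, so the share of each cause stays open, and no biological explanation was tested.

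Isl1 UMIs were found in every class tested. Free RNA of neuron-like nuclei as their source in epithelium-like nuclei is argued against, because the ratio of Isl1 to Pou4f1 UMIs was 128 and 168 there and 4.19 and 4.37 in neuron-like nuclei, a ratio at least 30.5 times as high. Free RNA of all nuclei remains a candidate source in mesenchyme-like nuclei, where the ratio was 0.78 times that of all nuclei as a mean of both replicates. The counting interval excludes 1 in replicate 1 (0.63, 0.43 to 0.97) and holds 1 in replicate 2 (0.93, 0.58 to 1.57), so that source can neither be held nor excluded. No biological explanation was tested.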

How the results depend on the processing

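The alternatives without the erythroid-like class, with halved ATAC counts, of the regions at both study genes and of the class shares without each replicate were chosen after the results were seen. Counts of genes and regions that passed stayed within 1.5 times of their reported values in the alternatives not named here. The splits of calls turned in some alternatives. With called doublets kept, 1333 genes passed against the other classes (2305 as reported) and 37686 regions against the other classes (69622 as reported). Between late and early clusters, which were picked anew from a new clustering, 1875 genes passed (588 as reported). The neuron-like share was then 13.1%, co-detection 1.01 times the expected number and the count of regions at both study genes 18 in place of 30. With glmTreat 271 genes passed between late and early clusters and 43318 regions against the other classes, as a stricter test would give. Otherwise the cause was not tested. The co-detection ratio was 1.00 unthinned, 1.07 thinned to 1000 UMIs, 1.05 with 5 depth bins and 1.04 without either replicate (1.043 to 1.045). The unthinned value was held near 1 by the detection of Isl1 in nearly all nuclei. The neuron-like share was 8.82% with ATAC classes and 10.3 to 10.9% without either replicate.

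With the replicate block, which pairs the class sums of a replicate, 2309 genes passed against the other classes, 2444 against epithelium-like nuclei and 599 between the clusters. The block gave 68336 and 91921 regions, 30 and 26 regions at both study genes, 12 of 12 contrasts of Isl1 and Pou4f1 and 22 of 36 list tests. It ended the call of the other cranial ganglion list against epithelium-like nuclei and brought in the transcription factor list between the clusters, a call lost again with an estimated correlation (adjusted p = 0.0952). With the preset correlation it changed no other list call. The blocked log2 fold changes of Isl1 were 1.34 against epithelium-like, 5.65 mesenchyme-like, 5.53 chondrogenic, 5.57 glia-like, 4.20 endothelium-like and 3.45 erythroid-like nuclei, and those of Pou4f1 were 6.41, 6.86, 6.80, 6.34, 6.03 and 3.94.

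Without either replicate, Isl1 ranged from 1.34 to 1.34 against epithelium-like, 5.59 to 5.71 mesenchyme-like, 5.46 to 5.60 chondrogenic, 5.33 to 5.85 glia-like, 3.96 to 4.47 endothelium-like and 2.80 to 4.51 erythroid-like nuclei. Pou4f1 ranged from 6.26 to 6.60, 6.69 to 7.08, 6.29 to 7.78, 5.64 to 7.87, 5.75 to 6.37 and 3.84 to 4.02. These are folds with no test, since a single replicate leaves no residual degrees of freedom, and counts of calls have no such value. Of the values of single named genes under an alternative, 403 kept to the spread between replicates and 35 moved past it, mostly without 1 replicate. Bcl6b went from −7.55 to −2.44 between the replicates alone, and Lfng stood at −1.41 and −0.56. Depth limits genes such as Bcl6b, which had 1 UMI in neuron-like nuclei, and the 7 classes tested range from 164852 to 40832155 UMIs per sum. With a 5 kb window the odds ratios of RNA and promoter accessibility, for higher and then lower RNA, were 7.94 and 4.44 against epithelium-like nuclei. They were 7.75 and 4.47 against the other classes. The motif test and its alternatives were not run, for want of a genome sequence.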

Other observations

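The gene levels by cluster in this part were chosen after the results were seen, and none of them was tested between clusters.

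Isl1 was unevenly spread over the epithelium-like clusters. The highest levels were in cluster 1, led by Tac1, Frzb and Rorb, with 768 and 825 CPM in replicates 1 and 2, in cluster 2, led by the tectorial membrane gene Tectb, with 724 and 712 CPM, and in cluster 0, led by genes that include Lgr5, with 673 and 701 CPM. Cluster 2 also held the prosensory genes Sox2 (169 and 176 CPM), Jag1 (282 and 310 CPM) and Fgf20 (166 and 196 CPM), and Lmx1a at 67.8 and 53.4 CPM. Cluster 11, also led by Tectb and with Jag1 at 284 and 290 CPM, had Isl1 at only 195 and 199 CPM. Clusters 6 and 16, led by Otx2 or the otoconial gene Oc90, held 52.6 and 50.3, and 100.3 and 56.4 CPM of Isl1. Lmx1a stood there at 736 and 696, and at 932 and 883 CPM. Pou4f1 ranged from 0 to 8.22 CPM over the 11 epithelium-like clusters.

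The otic transcription factor gene Gata3 stood at 1287 and 1313 CPM in cluster 0 and at 130 and 113 CPM in cluster 6. Oc90 stood at 5056 and 5488 CPM in cluster 6 and 4550 and 5004 CPM in cluster 16, and Otx2 at 470 and 491 CPM in cluster 6. In cluster 14 (322 and 370 nuclei), where Tac1 and Msx1 led, Isl1 stood at 576 and 603 CPM.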
